A study of Mus musculus with 120 samples.

How the data were processed

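DNA methylation was measured by whole-genome bisulfite sequencing in hippocampus and blood of wild-type and App-NLGF knock-in mice at postnatal weeks 3, 8 and 24. Per the labels' protocols, genomic DNA was sheared, made into libraries with the NEBNext Ultra II kit, converted with the EZ DNA Methylation-Gold kit and amplified with a uracil-tolerant polymerase, and DNA of the 2 tissues was extracted with different kits. Bisulfite turns unmethylated cytosine into uracil and leaves methylated cytosine, so incomplete conversion reads as methylation. Samples were grouped by tissue, genotype and age from their titles, which gave 12 groups of 10 libraries with 5 of each sex.

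Per the submitters' processing notes, FastQC, Trim Galore, Bismark and methylKit were used with the mm10 build, and their versions are not given in the sources used here. Per the series' design text, the genotypes were compared in each tissue and age with sex as a covariate. The p-values and adjusted p-values used here are the authors' own, as deposited, for windows of 1 kb on a fixed grid. The authors' deposited list holds 8961 windows, and tests on the list itself found every adjusted p under 0.1 and every absolute difference at least 10 percentage points. The test statistic, the coverage filter and the adjustment method behind these values are not given in the sources used here. The deposited methylation difference is in percentage points, and its sign was read as App-NLGF minus wild type. Columns of values per library used here numbered 0. Depth is therefore unknown, no coverage stands behind any printed difference, and a difference from few reads cannot be told from one with many. The list holds called windows alone, so a window absent from it did not differ, missed a threshold or was too thinly covered.

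The number of windows tested in each comparison was recovered from the ratio of p to adjusted p, which under the Benjamini-Hochberg method is a whole rank over the number of tests. Between 79.2% and 91.1% of these ranks came out whole within a tolerance of 0.02, and 2303864 to 2330500 windows were recovered per comparison. This rests on the assumption that the method was Benjamini-Hochberg.

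Windows were assigned to every gene whose body they overlapped or lay within 10 kb of, using the gene table of the GRCm38.p6 assembly, which has the same coordinates as mm10 for the chromosomes used. Its genes on X and the autosomes, 49554 in number, formed the background, 21631 of them coding. Strand, exons and genome sequence were not used here. A window shared by overlapping genes counts for each of them. The 9 windows on unplaced scaffolds stayed in the counts of windows and were left out of analyses by position.

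The comparisons, 23 gene lists, tests and alternatives were fixed before the data were examined. The lists cover App processing, Alzheimer risk loci, glial, neuronal, vascular and blood cell markers, synapses, channels, axon guidance, immediate early genes, imprinting, chromatin, developmental transcription factors, insulin and autophagy, and the circadian clock. Shares of higher windows were tested with an exact binomial test and compared with Fisher's exact test, and median absolute differences were compared by permutation with 100000 resamples, all two-sided. Overlaps were counted from 1 bp and set against 1000 random placements on the same chromosome. The share of windows per chromosome was tested against its share of the length. Gene lists were tested with Fisher's exact test against all genes. Because long genes hold more windows, each list was also set against 10000 random lists drawn from 50 bins of gene length. The length-matched result is the one given for each list. The random lists came from all background genes, coding or not, so coding status was not matched. Benjamini-Hochberg adjustment was applied within each family, with calls at an adjusted p under 0.05. Each gene list test covered all lists and comparisons together. Intervals are exact Clopper-Pearson at 95% and describe the lists of windows, not animals.

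Alternatives kept windows with an adjusted p under 0.001, kept windows of at least 15 points, merged windows within 10 kb, left out chromosome 16 or X, counted overlaps within 5 kb, or changed the gene background. Windows at gene ends, meaning within 1 kb of the start or end of a coding gene, gene families, chromosome X and the gene-body assignment were added after the data were seen.

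Named genes follow a rule fixed in advance. It took, per comparison, the 5 largest increases, the 5 largest decreases and the 5 smallest adjusted p among windows assigned to a named gene that is not a predicted one, and up to 12 members of the gene lists by size. It also took up to 10 genes with a window at all 3 ages of a tissue, up to 10 with a window in both tissues at the same age, and genes with a window within 1 Mb of App. Further examples from lists that passed a test, from windows in more than 1 list and from gene families were chosen after their values were seen. Some genes that the rule takes are not reported here.

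The list tests were checked on simulated data before use. Among 460 list tests on randomly placed windows the all-gene Fisher test called 60 and the length-matched test 0, and both called a planted list in 20 of 20 runs. The plant added windows at 20 of the 30 presynaptic release genes, so power for a smaller excess was not checked. Random placement does not gather windows at gene ends or near one another. The check therefore does not cover false calls in a list whose windows are gathered so, such as the longest one. Rank recovery came within 50 tests of the truth in 3 of 3 runs. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.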

Results

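Whole-genome bisulfite sequencing measured DNA methylation in hippocampus and blood of App-NLGF knock-in mice and wild-type mice. App-NLGF mice carry a humanised amyloid-beta sequence with Swedish, Iberian and Arctic mutations in their own App gene and form amyloid plaques without overexpressing the precursor protein. The labels give 120 libraries, 60 per tissue, in 12 groups of 10 that combine tissue, genotype and postnatal week 3, 8 or 24, with 5 libraries of each sex in every group. The genotypes were compared within each tissue and age with sex as a covariate, which asks how early methylation differs between them and whether blood shares the differences seen in hippocampus. The values used here are the 1 kb windows that the authors called, each with a methylation difference in percentage points, a p-value and an adjusted p-value. Methylation levels, coverage and values per library were not analysed here, so the depth behind each difference is unknown and no spread between animals can be given. Differences are read as App-NLGF minus wild type, an order that rests on the name of the comparison alone, so every direction below would flip if the order were the reverse. Positions are on mm10. The gene annotation used gives gene bodies without strand or exons, so a window is placed inside a gene or at a distance from it, and promoter, exon and intron are not separated. A value printed for a gene is that of a single window. Windows of both signs lay in Mgat4c and Cntnap2 in hippocampus at week 3, in Epha6 and Fam91a1 in hippocampus at week 8, in Kcnma1 in hippocampus at week 24, and in Epha6, Erbb4, Lrrc4c, Lsamp and Tcra in blood at week 8, so for these genes the printed value gives no direction of the gene as a whole.

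The 6 comparisons together held 8961 windows, all with an adjusted p under 0.1 and an absolute difference of at least 10 percentage points. Hippocampus had 1024 windows at week 3, 742 at week 8 and 949 at week 24. Blood had 1153 windows at week 3, 4526 at week 8 and 567 at week 24. At week 3 most hippocampal windows were lower in App-NLGF, with 29.5% higher (95% Clopper-Pearson interval 26.7 to 32.4, 302 of 1024). At weeks 8 and 24 the balance lay on the other side, with 54.6% (50.9 to 58.2) and 58.6% (55.4 to 61.7) higher. Blood windows were mostly higher at week 3 (63.2%, 60.4 to 66.0) and week 24 (82.5%, 79.2 to 85.6), and mostly lower at week 8, where 11.1% (10.2 to 12.04) were higher. Each share differed from an equal split by an exact two-sided binomial test (adjusted p = 0.0139 for hippocampus at week 8, the largest of the 6). The hippocampal splits at weeks 8 and 24 did not hold among windows of at least 15 points, where 51.4% (p = 0.677) and 54.8% (p = 0.0678) were higher. The split at week 8 was also lost without windows within 1 kb of the start or end of a coding gene, at 53.0% (p = 0.123). Windows are not independent animals, so these tests describe the deposited lists.

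**Figure D1:**
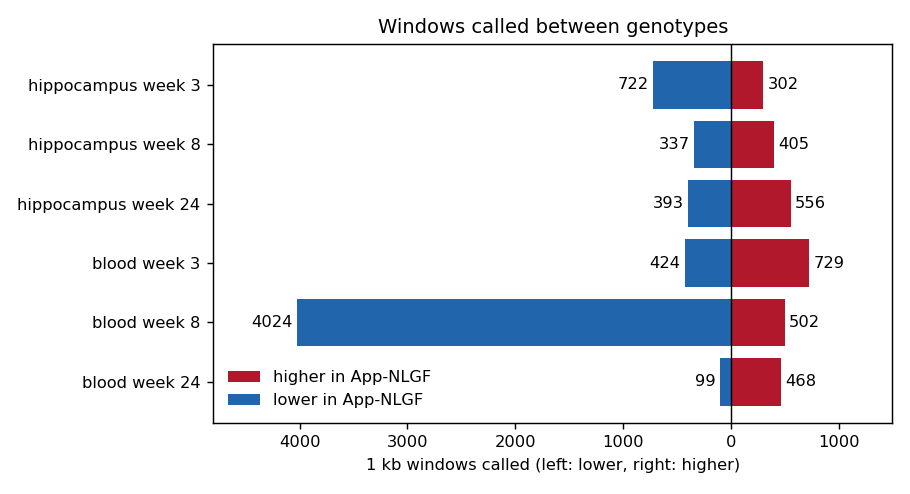
Number of 1 kb windows called between genotypes in each tissue and age, with windows higher in App-NLGF drawn to the right and lower ones to the left of 0. The list from blood at week 8 holds 4024 lower and 502 higher windows, and blood at week 24 holds 99 lower and 468 higher.

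In hippocampus at week 3, genes of axon guidance and cell adhesion had a window more often than length-matched genes. Of the 52 genes in this list 14 had a window, where length-matched random lists gave 5.67 on average (central 95% 2 to 10, adjusted p = 0.0442), with 6 windows higher and 10 lower. The direction of these windows was not tested against that of the whole list, of which 70.5% were lower. Of 21631 coding genes 562 had a window here, and of all 49554 genes 886, so the test did not hold coding status equal. Length within a bin was not matched either. The authors' deposited table gives -26.8 points at Plxna2, a semaphorin receptor, and 24.1 points at Cntnap2, a neurexin-family adhesion protein of axons, which also held 2 lower windows. In the authors' deposited table Ncam2, a neural cell adhesion molecule, stood at 20.6 points, Cdh13 at -18.4 points and Epha3, an ephrin receptor, at -17.8 points. Of 45 glutamate receptor and postsynaptic genes 6 had a window, with 1 window higher and 7 lower, a count inside the range of length-matched lists (1 to 8). Among them was the metabotropic receptor Grm7 at -20.6 points in the authors' deposited table. Presynaptic release genes had 4 of 30 members with a window (length-matched mean 1.98), including Unc13c at -19.2 points and the calcium sensor Syt1 at 18.7 points in the authors' deposited table. Zbtb20, a transcription factor of hippocampal pyramidal neurons, was at -19.8 points and the microglial receptor Gpr34 had a window 3.65 kb away at 19.4 points in the authors' deposited table. The call for axon guidance genes was lost when only gene bodies were counted (adjusted p = 0.0690) and when windows within 1 kb of the start or end of a coding gene were left out (adjusted p = 0.0938).

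The largest increases in named genes at this age lay inside Mgat4c, a glycosyltransferase gene, at 30.4 points (chromosome 10, 102143001 to 102144000, adjusted p = 6.87e-05), and inside Mrtfb, a serum response factor coactivator, at 28.9 points in the authors' deposited table. Other increases in the authors' deposited table were 28.8 points at Cdh19, a cadherin, and 22.8 points at Pate2. The largest decreases near named genes in the authors' deposited table were -28.0 points 4.14 kb from the olfactory receptor gene Olfr809 and -27.7 points near Olfr1492-ps1. After these and Plxna2 came -26.6 points at Lrrc7, a postsynaptic scaffold gene, and -26.2 points at Jarid2, a Polycomb cofactor, in the authors' deposited table. The smallest adjusted p of all 6 lists belonged to a window inside Mettl27 (chromosome 5, 134932001 to 134933000), with -12.2 points and an adjusted p of 1.63e-13 in the authors' deposited table. Other windows with small adjusted p in the authors' deposited table were Bcl9l, 6.74 kb away, at -11.5 points, Adamts5, an aggrecan-cleaving protease gene, at -13.3 points, and Mfsd4b4 at -13.8 points.

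In hippocampus at week 8, no gene list passed the length-matched test, and the named windows were divided between the directions. The list of calcium and potassium channels had 4 of 35 genes with a window (length-matched mean 3.04) and included Cacna1b at 13.5 points in the authors' deposited table. NMDA receptor subunit genes went both ways in the authors' deposited table, with Grin2a at -19.3 points and Grin2b at 14.7 points. Among axon guidance genes, 4 of 52 had a window (length-matched mean 4.93), and the authors' deposited table lists Epha6 at 23.5 points, Plxna4 at -19.7 points and Robo2 at -18.1 points. Also listed in the authors' deposited table were Lhx9, with a window 7.16 kb away at 13.9 points, and Ece1, which encodes an enzyme that degrades amyloid-beta, 6.24 kb away at 14.9 points. The synaptic vesicle gene Syn2 was at -15.6 points and the platelet integrin gene Itga2b at 16.9 points in the authors' deposited table. In named genes the largest increases in the authors' deposited table were Ggact at 33.5 points, Dach2 on X at 29.3 points, Vmn1r224 at 27.8 points, Fat3 at 25.8 points and Pramel33 at 25.5 points. In named genes the largest decreases in the authors' deposited table were Dennd1a at -32.9 points, Lrrc4b, a synaptic adhesion gene, at -31.5 points, Mageb18 at -29.4 points and the kinase gene Pak3 at -29 points. The smallest adjusted p of named genes in the authors' deposited table fell at Pard6g, a cell polarity gene, with -15.6 points (0.000100), Shroom3 with -16.1 points, Exoc4, an exocyst subunit gene, with 12.3 points, Fam91a1 with 10.3 points and the mitochondrial fission gene Fis1 with 20.4 points. Higher windows lay within 1 kb of the start or end of a coding gene more often than lower ones, at 30 of 403 (7.44%) against 4 of 337 (1.19%) by Fisher's exact test (adjusted p = 8.11e-05).

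In hippocampus at week 24, when amyloid deposits are established in this model, glutamate receptor and postsynaptic genes had 10 of 45 members with a window. This lay above the central 95% of length-matched lists (mean 4.02, 1 to 8) and did not pass after adjustment (adjusted p = 0.150), with 3 windows higher and 7 lower. In the authors' deposited table the kainate receptor gene Grik3 was at 17.3 points, the scaffold gene Homer2 at 15.6 points and the adhesion gene Nlgn1 at -15.8 points. Axon guidance genes had 9 of 52 members with a window (length-matched mean 5.54), led in the authors' deposited table by the ephrin receptor Ephb1 at 40.8 points (chromosome 9, 102295001 to 102296000, adjusted p = 2.49e-05). Dscaml1 at -21.8 points and Epha7 at -17.6 points followed in the authors' deposited table. Calcium and potassium channel genes had 5 of 35 members with a window (length-matched mean 3.46), among them Kcnma1 at -24.0 points and Cacna1e at 23.3 points in the authors' deposited table. Single members of other lists in the authors' deposited table were the methyl-CpG-binding domain gene Mbd5 at -17.9 points, the interferon regulator Irf1, 4.01 kb away, at -17.4 points, and the astrocyte transporter gene Slc4a4 at 16.2 points. Other large increases at named genes in the authors' deposited table were 28.3 points near Cldn34-ps, 27.6 points at Cfap53, 27.5 points at Sult2a5 and 25 points at Klhl32. The largest decreases at named genes in the authors' deposited table were -37.0 points at Fyco1, an autophagosome transport gene, -26.0 points at Lrfn5, -25 points at Lingo2 and -24.1 points 8.15 kb from Grap2. Small adjusted p in the authors' deposited table also marked Scpep1, 1.56 kb away, at -11.1 points, Arap2 at 17.7 points, Cwf19l2 at -17.6 points and Nckap5l at 12.2 points.

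In blood at week 3, higher windows prevailed and no gene list passed the length-matched test. Axon guidance genes had 11 of 52 members with a window (length-matched mean 6.49, adjusted p = 1.00), with 8 windows higher and 5 lower. Members in the authors' deposited table were Dscam at -24.4 points, Cntnap5a at -19.6 points, Ncam2 at 18.1 points, Unc5a at 17.4 points and Sema3c, 5.73 kb away, at -17.1 points. The list of DNA methylation and chromatin regulators had 4 of 38 members with a window (length-matched mean 1.88), among them the histone deacetylase gene Hdac4 at 23.7 points in the authors' deposited table. Immune and metabolic members in the authors' deposited table were Foxp3, the regulatory T cell factor on X, at 18.8 points and Foxo3 at -17.3 points. Among named genes the largest increases in the authors' deposited table were Slc24a3, a sodium-calcium exchanger gene, at 44.3 points, Lrrc7 at 37.9 points, Cpq at 35.4 points, Ccdc24 at 32.3 points and Upf3b, 4.53 kb away, at 31.7 points. Among named genes the largest decreases in the authors' deposited table were Nrxn3, a presynaptic adhesion gene, at -31.7 points, Magea5 at -29.3 points, Mctp1 at -29.1 points, Slc35f1 at -28.9 points and Xpo6 at -27.1 points. The smallest adjusted p in the authors' deposited table belonged to Chd9 at 14.9 points and Caln1 at -14.8 points, both with 2.14e-05. They were followed in the authors' deposited table by Wdr11 at 15.5 points, Rbm20 at 18.7 points and the thyroid hormone receptor gene Thrb at 17.9 points.

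In blood at week 8, lower windows dominated and many lay at gene ends. Developmental transcription factor, inhibitory neuron and postsynaptic genes had a window more often than length-matched genes, in a test that pooled higher and lower windows. Of the whole list 88.9% were lower, and direction was not tested against that share. The length-matched genes were drawn from all genes. Of 21631 coding genes 4217 had a window here, and of all 49554 genes 6102, so the test did not hold coding status equal. Gene ends were taken as a category only after the values were seen. Of 4525 windows placed on X or an autosome, 1895 (41.9%, 95% interval 40.4 to 43.3) lay within 1 kb of the start or end of a coding gene, where 4.33% of the grid does. Of lower windows 46.8% lay there and of higher windows 2.39%, and 99.4% of the windows at gene ends were lower. Windows at gene ends made up 709 of the 944 windows with an adjusted p under 0.001. Without them 2631 windows remained in the list, and 81.4% of those placed on a chromosome were lower. The other 5 lists had 3.54% to 6.26% of their windows at gene ends, and of these hippocampus at week 3, at 6.26%, also differed from the grid (adjusted p = 0.0129). Developmental transcription factors had 30 of 54 members with a window against 8.54 in length-matched lists (4 to 14, adjusted p = 0.0138), and all 48 windows were lower. Examples in the authors' deposited table were Sox6 at -15.4 points, the B cell factor Pax5 at -14.1 points, the eye and forebrain factor Six3 at -13.7 points and Hoxa3, 4.93 kb away, at -13.5 points. Inhibitory neuron markers had 11 of 18 members with a window against 3.28 (1 to 7, adjusted p = 0.0138), with 15 windows lower and 1 higher. The authors' deposited table gives the interneuron factor Lhx6 at -12.9 points, the GABA-synthesising enzyme gene Gad2 at -12.7 points, Dlx5 at -12.5 points and Erbb4 at 16.3 points. Glutamate receptor and postsynaptic genes had 27 of 45 members with a window against 13 (7 to 19, adjusted p = 0.0138), with 33 windows lower and 7 higher. Among these, the authors' deposited table gives Grid1 at 19.99 points, Nrxn3, a presynaptic adhesion gene held in this list, at -18.8 points and Grm7 at -16.1 points. These 3 lists kept an adjusted p of 0.0138 against length-matched lists when windows at gene ends were left out. That setting removed only windows within 1 kb of a start or end, so lower windows further away stayed in the test. All 33 windows left to developmental transcription factors were lower.

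Blood cell markers were not over-represented in this list. Of 28 lymphocyte markers 4 had a window in blood at week 8 (length-matched mean 4.48), of 16 erythroid and megakaryocyte markers 4 (mean 2.09), and of 20 myeloid markers 0 (mean 2.48). Alzheimer risk loci had 16 of 42 members with a window, all lower, above the length-matched range (mean 8.02, 3 to 13) and not past adjustment (adjusted p = 0.133). Without windows at gene ends 6 members had a window, inside the length-matched range (mean 3.76, 1 to 8). Axon guidance genes had 25 of 52 members with a window (mean 16.7, adjusted p = 0.334) and calcium and potassium channels 17 of 35 (mean 10.8, adjusted p = 0.527). Members of these lists in the authors' deposited table included Lsamp at -30.2 points, Epha6 at 27.5 points, Cntn6 at -21.7 points, Dscam at -21.3 points and the potassium channel gene Kcnq3 at 19.1 points. Of windows at named genes the largest increases in the authors' deposited table were the melanin enzyme gene Tyr at 34.5 points, Lrrc4c at 29.9 points, the T cell receptor alpha locus Tcra at 28.3 points and the lymphoid regulator Ikzf1 at 26.2 points. Of windows at named genes the largest decreases in the authors' deposited table were Pcdh11x at -38.1 points, Tulp3 at -33.9 points, Cpne4 at -27.5 points and a window 3.48 kb from Olfr769 at -26.3 points. The smallest adjusted p of named genes marked moderate decreases in the authors' deposited table, at Zfp81 with -10.4 points (1.81e-13), Med22 with -10.1 points, Rab12 with -11.5 points, Hmmr with -10.05 points and Scfd2 with -11.4 points.

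**Figure D2:**
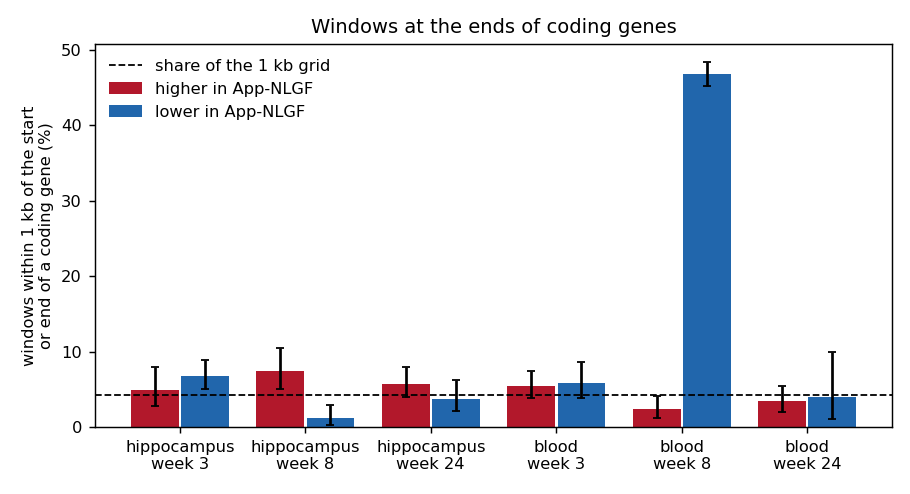
Percentage of higher (red) and lower (blue) windows of each list that lie within 1 kb of the start or end of a coding gene, with 95% Clopper-Pearson intervals, and the share of the 1 kb grid that does so (dashed, 4.33%). Lower windows of blood at week 8 stand at 46.8%, and lower windows of hippocampus at week 8 at 1.19%.

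In blood at week 24, higher windows dominated and Alzheimer risk loci carried more windows than length-matched lists. Of the 42 loci 6 had a window against 0.770 in length-matched lists (0 to 3, adjusted p = 0.0138), and all 6 windows were higher. Of the whole list 82.5% were higher, and no gene list was tested for direction against that share. Of 21631 coding genes 270 had a window here, and of all 49554 genes 466, so the test did not hold coding status equal. In the authors' deposited table the 6 loci were Cd2ap, 6.29 kb away, at 15.7 points, the kinase gene Ptk2b at 13.5 points, the myeloid receptor gene Cd33, 9.58 kb away, at 11.1 points, the sorting receptor gene Sorl1 at 10.6 points, the tau gene Mapt at 10.3 points and Cntnap2 at 10.2 points. With gene bodies alone 4 of the 42 loci had a window and the call was lost (adjusted p = 0.106). Axon guidance genes had 9 of 52 members with a window, all 9 windows higher, above the length-matched range (mean 3.48, 0 to 7) and not past adjustment (adjusted p = 0.245). The authors' deposited table gives the guidance receptors Robo1 at 17.4 points and Robo2 at 15.1 points, the contactin gene Cntn4 at 17.3 points, Cdh13 at 14.2 points and Lsamp at 13.8 points. Other list members in the authors' deposited table were the synapsin gene Syn1 on X at 18.2 points, Cacna1d at 17.7 points, Hdac9, 2.58 kb away, at 15.9 points, Grm8 at 15.7 points and Gria1, 3.76 kb away, at -14.6 points. Large increases in the authors' deposited table were Egfem1 at 38.9 points, the protocadherin alpha cluster at Pcdha1 at 23.7 points, Gpc5 at 23.3 points and Nap1l3 on X, 2.56 kb away, at 23.2 points. Decreases in the authors' deposited table were -34.4 points near Olfr112, -26.0 points near Olfr681, -24.8 points at the adenosine kinase gene Adk, -23.7 points at Macrod2 and -21.9 points at Rbpms. The smallest adjusted p in the authors' deposited table was 0.00136, at Lsamp, Cntn4 and Uvssa (-12.7 points), followed by Galnt17 at 16.3 points.

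**Figure D3:**
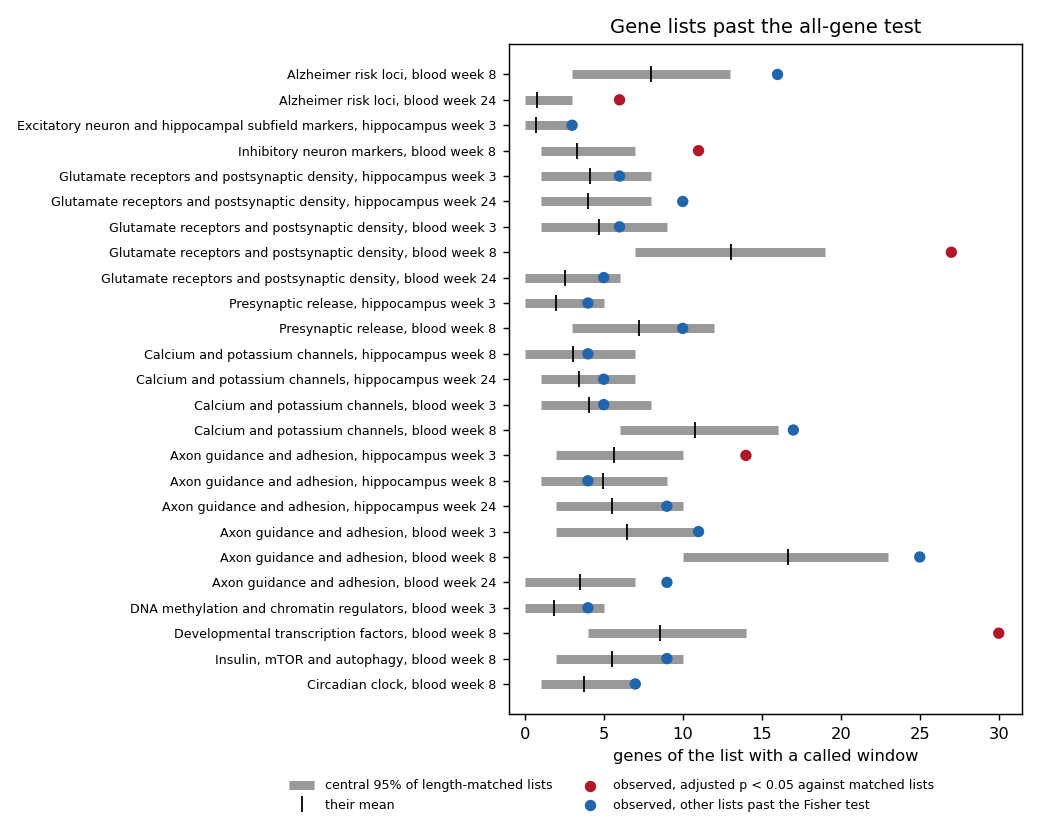
Number of genes with a called window (points) for each gene list and comparison that passed the all-gene Fisher test, beside the mean (tick) and central 95% (bar) of 10000 length-matched random lists. Red points passed the length-matched test after adjustment, such as developmental transcription factors in blood at week 8 with 30 genes against a mean of 8.54, and blue points did not.

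The share of higher windows and the size of the differences were compared between ages and tissues. These tests took windows as units, not animals, so they compare the deposited lists. The medians are of windows cut at the deposited minimum difference and adjusted p. They cannot tell a change in methylation difference from a change in which windows passed these thresholds. By two-sided Fisher's exact tests, 8 of 9 differences in the share of higher windows between ages or tissues passed adjustment, and hippocampus at weeks 8 and 24 did not differ (4.01 points, adjusted p = 0.103). The median absolute difference was 13.8 points at week 3, 13.5 at week 8 and 14.0 at week 24 in hippocampus, with no pair of ages apart by permutation tests (adjusted p of 0.14 or more). In blood it was 14.9 points at week 3, 11.7 at week 8 and 14.0 at week 24. Week 8 minus week 3 was -3.22 points and week 24 minus week 8 was 2.28 points (adjusted p = 2.2e-05 for both, the smallest these resamples can give). Week 24 minus week 3 was -0.948 points (adjusted p = 0.00045). Blood minus hippocampus was 1.07 points at week 3 and -1.86 points at week 8 (adjusted p = 2.2e-05 for both), and -0.0465 points at week 24 (adjusted p = 0.81).

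Shared windows were few in number. Of 8933 distinct windows on X and the autosomes, 18 were in more than 1 list and 1 of these was in 3. The window in 3 lists, on chromosome 16 at 79105001 to 79106000 with no gene assigned, was at -31.9 points in hippocampus at week 3, -36.7 points in blood at week 3 and -24.8 points in blood at week 8 in the authors' deposited table. Hippocampal lists of different ages shared 3 windows (0.898 by random placement, p = 0.126) and blood lists shared 3 (3.19 by placement, p = 1.00). Hippocampus and blood shared 3 windows at the same age (1.91 by placement, p = 0.593) and 11 between different ages (4.49 by placement, p = 0.00599). Over all pairs of lists 20 shared windows were observed against 10.5 by placement (p = 0.0160), of which 13 had the same sign. Placement drew from all positions of a chromosome, tested or not. By the recovered numbers of tested windows, the expected counts were higher, at 11.98 over all pairs and 5.12 between tissues at different ages. None of the 60 overlap relations computed passed Benjamini-Hochberg adjustment (smallest adjusted p = 0.320). The window inside Mettl27 was among them, at -12.2 points in hippocampus at week 3 and -11.1 points in blood at week 8 in the authors' deposited table. Shared in the same direction between hippocampus at week 3 and blood at week 8 were also Tns1, a focal adhesion gene, at -12.9 and -10.1 points and Srp54b at -17.3 and -14.0 points in the authors' deposited table. Opposite directions were seen at Eif4a3, an RNA helicase gene, with -11.6 points in blood and 11.5 points in hippocampus at week 8 in the authors' deposited table. At the level of coding genes, the pairs of lists shared 937 genes against 930 by placement (p = 0.843). Genes with a window at all 3 ages numbered 3 in hippocampus and 13 in blood. In hippocampus these were Nell1, Pcdh9, a protocadherin gene, and St8sia2, which makes polysialic acid on neural cell adhesion molecules. The authors' deposited table gives Nell1 at -19.0, -26.8 and -12 points at weeks 3, 8 and 24, Pcdh9 at 13.4, 20.7 and 13.1 points, and St8sia2 at -12.6, -14.9 and 11.2 points, in each case in different windows. In blood the list was made of long genes such as Lsamp, Gpc5, Nrxn3, Lingo2, Macrod2, Cdh13 and Rbfox1 and of the antigen receptor loci Igh and Tcrb. Genes with a window in both tissues at the same age numbered 40, 113 and 25 at weeks 3, 8 and 24. Lrrc7 at week 3 stood at -26.6 points in hippocampus and 37.9 points in blood in the authors' deposited table, in different windows.

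No window lay inside App (chromosome 16, 84952666 to 85175255) or within 10 kb of it, and 10 lay within 1 Mb, where 7.56 would fall by length. In the authors' deposited table these included Cyyr1, the nearest coding gene on the side of higher coordinates, at -21.2 points in hippocampus at week 8, the metalloprotease gene Adamts1 at -10.5 points in blood at week 8, and Adamts5 at -13.3 points in hippocampus at week 3 and -11.5 points in blood at week 8. A window with no gene within 10 kb, at 86113001 to 86114000, was at -14.9 points in hippocampus at week 24 and -16.0 points in blood at week 8 in the authors' deposited table. The share of windows on chromosome 16 did not differ from its share of the genome in any of the 6 lists after adjustment. In blood at week 8 chromosomes 11 (6.74% of windows, 1.45 times its length share, adjusted p = 2.61e-08) and 17 (4.69%, 1.30 times, adjusted p = 0.00701) did by exact binomial tests. So did X in blood at week 24 (12%, 1.86 times, adjusted p = 7.63e-05). These tests used length alone and made no allowance for the genes on a chromosome. In blood at week 8, 41.9% of windows lay at gene ends. On X 94.1% of the windows in blood at week 24 were higher against 80.9% on the autosomes, and in hippocampus at week 24 75.4% against 57.3% (Fisher's exact test, adjusted p = 0.0175 for both). In all 6 lists the median absolute difference was larger on X than on the autosomes. It was 15.7 against 13.7 points in blood and 17.0 against 13.9 points in hippocampus at week 24. Depth on X is unknown, so differences from few reads there cannot be told apart.

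**Figure D4:**
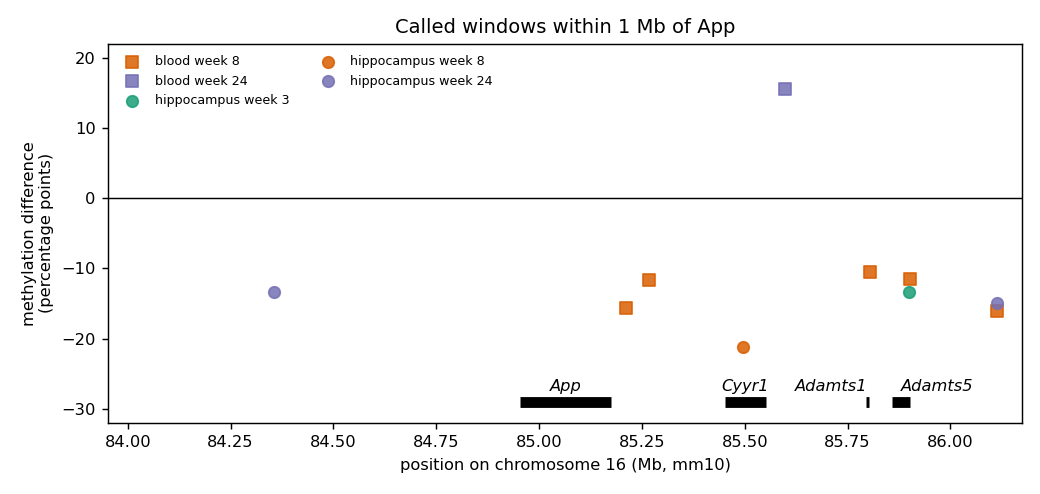
Methylation difference in percentage points of the 10 windows called within 1 Mb of App against their position on chromosome 16 (Mb, mm10), with squares for blood, circles for hippocampus and colours for the week, and gene bodies as black bars. No window falls in App, and Adamts5 carries a window from hippocampus at week 3 (-13.3 points) beside one from blood at week 8 (-11.5 points).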

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

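Of the tests in this part, those on the direction of the blood windows at week 8 were chosen after the result was seen, and those on windows near App, on windows in both tissues and on gene length were set beforehand. The share of windows higher in App-NLGF differed between ages or tissues in 8 tests of the difference itself. In hippocampus it was 25.1 percentage points higher at week 8 than at week 3 and 29.1 points higher at week 24 than at week 3. In blood week 8 minus week 3 was -52.1 points, week 24 minus week 3 was 19.3 points and week 24 minus week 8 was 71.4 points. Blood minus hippocampus was 33.7 points at week 3, -43.5 points at week 8 and 24.0 points at week 24.

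The blood list at week 8 held 4526 windows, 88.9% of them lower, and 41.9% lay at gene ends. At 15 points or more it held 583 windows, against 228 to 565 in the other lists. The number of windows tested argues against more testing as the source, since it was 0.990 times the mean of the other comparisons while the list was 5.11 times as long. Incomplete bisulfite conversion in wild-type libraries is a candidate explanation that stays open. Ribosomal protein genes, whose promoters are unmethylated across cell types, had a lower window at their ends in 27 of 77 cases. Other coding genes had one in 2127 of 21554 cases (odds ratio 4.93, p = 2.33e-09, Fisher's exact test). Gene starts were not told from gene ends, and the other genes were not matched for promoter type. Any cause acting at such gene ends could give this excess, so the test cannot single out conversion. A shift in blood cell composition was left undecided, as 8 of 64 blood cell marker genes had a window against 9.09 in length-matched lists (4 to 15). A loss of methylation with genotype at this age was not tested and stays open, since values per library were not used here.

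Windows found in more than 1 list formed the next pattern, and their number did not pass adjustment. Within 20 Mb of App lay 134 of 8933 distinct windows (1.5%, 1.26 to 1.77) against 1.26% of the length (p = 0.0461, exact binomial test). Sequence variants carried along with the knock-in may account for some, since 2 of these 134 recurred in the other tissue with the same sign against 7 of 8799 elsewhere (odds ratio 19.03, p = 0.00750), 1 of the 2 being the window in 3 lists, but without 1 of them the odds ratio was 9.52 (p = 0.113). Strain or colony variants against the reference were left undecided, as 9 of 13 windows in both tissues had the same sign (69.2%, 38.6 to 90.9), while 1 of these 13 was in more than 2 lists against 5 of 8920 windows of a single tissue called at more than 1 age, a difference that rests on 1 window and was not tested. Shared biology of the tissues was not tested apart from these.

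Gene lists rich in long genes held many windows. Of 25 list and comparison pairs past the all-gene Fisher test, 15 had a count inside the central 95% of length-matched lists, so gene length could account for these. The other 10 lay above that range, and 5 of those 10 passed adjustment against length-matched lists. For the 5 that passed, this argues against differences in length between the bins as the whole source. Those that did not pass stay undecided. Length within a bin was not matched, so for lists with very long genes a remaining effect of length stays open. The random lists were drawn from all genes, coding or not, so an effect of coding status stays open too.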

How the results depend on the processing

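The alternatives that left out windows at gene ends, the chromosome X shares and the median at 15 points were chosen after seeing the data. The sign of the majority of windows turned in no comparison under an alternative that left windows to count. No paired analysis was possible because no values per library were used here, and for the same reason leave-one-out and the replicate block were not run. Depth is unknown, so which windows rest on few reads was not examined. Values below run in the order hippocampus weeks 3, 8 and 24, then blood weeks 3, 8 and 24.

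At an adjusted p under 0.001 the lists held 5, 8, 17, 13, 944 and 0 windows, so blood at week 24 gave no share or median. The share of higher windows was then 20%, 62.5%, 64.7% and 61.5% in the first 4 lists and no longer past the test, with fewer windows tested. Shared windows then numbered 0 between hippocampal ages, 0 between blood ages and 0 between tissues at the same age (tissues at different ages were not run), and 0, 0, 0, 0, 3 and 0 gene lists passed the all-gene Fisher test. Chromosome X then held 0.847% of windows in blood at week 8, past the test. At 15 points or more there were 405, 282, 389, 565, 583 and 228 windows. The share of higher windows fell short of the test in hippocampus at weeks 8 (51.4%) and 24 (54.8%), and the median absolute difference was 18.5 points in hippocampus and 17.3 points in blood at week 8, by construction of the minimum. Without windows at gene ends blood at week 8 held 2631 windows, and the share in hippocampus at week 8 was 53.0%, no longer past the test. Within 5 kb the shared windows numbered 12 between hippocampal ages, 23 between blood ages and 23 between tissues at the same age. A wider distance counts more, and random placement gave 10.2, 35.0 and 21.0. With all windows 4, 2, 3, 4, 9 and 3 gene lists passed the all-gene Fisher test, and against length-matched lists 1, 0, 0, 0, 3 and 1 passed. Without chromosome 16 the all-gene Fisher test called 1 list in hippocampus at week 8 in place of 2 and 3 in hippocampus at week 3 in place of 4, and without windows at gene ends it called 6 in blood at week 8 in place of 9. Other than where construction shows it, the cause was not tested. Merging windows within 10 kb or leaving out X changed no call on the share of higher windows.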

Other observations

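Gene families and the neighbourhood of windows were examined only after the lists had been seen. Families too were set against length-matched genes drawn from all genes, coding or not. In blood at week 8, ribosomal protein genes had 30 of 77 members with a window against 8.54 in length-matched lists (4 to 14, adjusted p = 0.0033), and all 32 windows were lower. Examples in the authors' deposited table were Rps15a at -13.4 points, Rpl29 at -13.2 points, Rps19 at -12.8 points and Rps23 at -12.2 points. The families with fewer genes hit than length-matched lists, past adjustment, were 3. Olfactory receptors had 24 members (2.16%) against 54.6 (adjusted p = 0.0033), vomeronasal receptors 10 of 355 against 28.01 (adjusted p = 0.0053) and keratins 0 of 53 against 7.20 (adjusted p = 0.0088). The keratin result was lost with gene bodies alone (adjusted p = 0.413). Clustered protocadherins had 38 of 57 members with a window in blood at week 8 and 12 at week 24, but these came from 4 windows and 1 window, since the genes overlap.

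The following lists, fixed beforehand, did not pass the length-matched test in any comparison. In blood at week 8 genes with a window numbered 8 of 28 for App processing and amyloid clearance, 7 of 30 for disease-associated microglia, 1 of 16 for homeostatic microglia and 5 of 25 for complement and interferon. They numbered 1 of 17 for astrocytes, 3 of 22 for oligodendrocytes and myelin, 7 of 22 for excitatory neurons and 3 of 18 for endothelial, pericyte and choroid plexus markers. They numbered 6 of 20 for immediate early genes, 6 of 42 for imprinted genes, 6 of 38 for chromatin regulators, 10 of 30 for presynaptic release, 9 of 26 for insulin, mTOR and autophagy and 7 of 20 for the circadian clock.

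Windows of blood at week 8 lay close together, with 562 having another within 10 kb against 156 by random placement (3.60 times, adjusted p = 0.012), and 94.3% of 296 neighbouring pairs had the same sign against 80.3% expected from the shares. In the other 5 lists 2 to 12 windows had such a neighbour, and none differed from placement after adjustment. Random placement did not gather windows at gene ends, where 41.9% of the blood windows at week 8 lay. The excess of neighbours in that list therefore cannot be told from its gathering at gene ends. In blood at week 8, 70.3% of windows lay in gene bodies against 48.5% of the grid (adjusted p = 1.68e-192), and in blood at week 24 43.4% did (adjusted p = 0.0491). The windows that passed the adjusted p regardless of size were recovered as 14312 in blood at week 8, of which 31.6% reached 10 points, against 56.0% to 73.3% in the other lists.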
